A study of Mus musculus with 12 samples.

How the data were processed

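RNA sequencing libraries of 12 samples of mouse tumour-associated macrophages were made with an Illumina TruSeq RNA kit after fragmentation of the RNA by heat, per the labels' protocols. The authors deposited 1 table per library with whole-number counts of reads per Ensembl gene, not normalized. The submitters' processing notes name Bowtie, TopHat 1.2.0, SAMtools 0.1.12a and HTSeq and the mouse build mm9 (NCBIM37). The counting mode and the use of strand are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart, and reads of near-identical genes can be split or lost. Each deposited count table holds 36439 genes and 5 summary entries that name no gene, which were kept out of library sizes and tests. Reads over no gene were 21.5% to 26.6% of each MRC1+ and 19.7% to 24.8% of each CD11c+ library, and 8.37% to 9.84% of each miR-511-3p and 7.64% to 10.4% of each mutated miR-511-3p library. Reads aligned to several places were 15.5% to 20.1% of the sorted and 12.8% to 13.3% of the overexpression libraries and were not counted to genes. This lowers the counts of gene families with near-identical members, such as ribosomal protein, haemoglobin and Cd209 genes. The sorted and the overexpression libraries were not compared with each other by a test, except in fits of all 12 libraries and in the ratio of Mir511 to Mrc1 counts.

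The reference annotation used here was GENCODE M21 on GRCm38, a later build than that of the counts, so no coordinates are given. It served for gene symbols, which 31819 of the 36439 gene identifiers received, and for 3′ UTR sequences. A 3′ UTR of at least 20 bases was found for 20920 genes, taking the longest per gene.

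Reads counted to genes ranged from 10824918 to 27890433 per library. Mir511, at the low end of what this depth measures, rests on 8 to 209 reads per group. Intervals of its read ratio are exact 95% binomial intervals and cover counting error only.

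Samples were grouped by the labels into 4 groups of 3. Within each group no pair of libraries agreed within sampling noise, with chi-square per degree of freedom of 10.0 to 36.4. This argues only against the same library being entered more than once, since separate preparations of the same RNA could also differ so. Each library was counted as a replicate on the numbering of the labels. The labels number the replicates, and whether the numbers pair the libraries was checked from the correlation across genes of the deviations of same-numbered libraries from their group means. It was 0.104, 0.337 and 0.250 in the sorted groups and 0.147, 0.258 and 0.462 in the overexpression groups. All lay above the limit of 0.1, so the numbers were treated as pairs, a pairing that comes from the data and not from the labels. The first miR-511-3p library correlated better with the second mutated library, at 0.166, than with its own number. A fit with the replicate number as a block was run beside each result.

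Both comparisons, MRC1+ against CD11c+ TAMs and miR-511-3p against mutated miR-511-3p TAMs, used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the 6 libraries compared, with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05. TMM CPM were computed from the same factors. The rule for named genes, fixed like the tests and lists in advance, took Mrc1, Itgax, Adgre1, Csf1r, Mir511 and Rock2, then the 10 genes with the largest log2 fold change in each direction among those that passed, had a mean of at least 10 CPM in the higher group and no overlap of the libraries. Where none passed, as under miR-511-3p, it took the 5 genes of lowest p in each direction, and for each list described up to 4 members of lowest p. Members of lists that are named without belonging to these 4 were chosen after their values were seen.

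The 27 gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. They comprised macrophage and antigen-presentation programmes, matrix, angiogenic, metabolic and cell cycle genes, markers of 8 other cell types, and mitochondrially encoded and ribosomal protein genes as signs of RNA quality. The matrix and fibroblast lists share members, and macrophages also express some of the genes in both. For miR-511-3p sites, genes with an 8mer, 7mer-m8 or 7mer-A1 match in the 3′ UTR were set against genes without one by camera. The mean difference within 10 bins of 3′ UTR length was ranked among 210 heptamers of the same base composition.

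The steps were tested on simulated counts drawn from the real means, with 200 changed genes. For MRC1+ against CD11c+ TAMs (15622 genes) 69.0% of 2-fold and 87.0% of 4-fold changes were recovered, 100% with the right sign, and 5.29% of calls were false. For miR-511-3p against its mutated form (14054 genes) these were 71.0%, 92.0%, 100% and 8.20%. A list of 20 genes shifted by 0.5 on the log2 scale gave a camera p of 1.80e-21 and 8.26e-23, and an unshifted list 0.410 and 0.227. The simulated genes were drawn independently of each other. This therefore does not test camera on lists whose genes move together, such as cell cycle genes under miR-511-3p (estimated correlation 0.821). For the sites, the real log2 fold changes of the second comparison were shuffled over genes in place of simulated counts. A shift of -0.05 then planted in site genes (11887 genes) came out at rank 1 of 210 heptamers, and without the shift at rank 151. That shift was larger than the observed matched difference of -0.0142, so detection of a difference of the observed size was not tested.

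Alternatives were the size factors of DESeq2 and upper-quartile scaling, no filter and a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of all 12 libraries, the replicate number as a block, a change of at least 2-fold, an adjusted p of 0.10, and leaving out each library. For lists and sets they were an estimated correlation, fry and the block, and for sites other site types, the shortest 3′ UTR and genes above the median expression. The newer quasi-likelihood method of edgeR, lists without Mrc1 and Itgax, sets from the sorted comparison without the first CD11c+ library, and the block combined with fry or an estimated correlation were added after the data had been seen. Mature microRNAs, exon-level counts and reads of the vectors were not analysed here. A list, and some members of other lists that the counts per list include, are not reported here.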

Results

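Gene expression was measured by RNA sequencing in 12 libraries of tumour-associated macrophages (TAMs), the macrophages found inside a solid tumour. They came from Lewis lung carcinomas, a transplantable mouse lung tumour, grown under the skin of C57BL/6 mice. The libraries formed 4 groups of 3. In both sorted groups the cells carried F4/80, a surface protein of mouse macrophages, together with either the mannose receptor MRC1 or the integrin CD11c. The remaining groups were F4/80+ TAMs that overexpressed miR-511-3p, a microRNA whose hairpin gene Mir511 lies within an intron of Mrc1, or a mutated form of it. The sequence of the mutated hairpin is not given in the sources used here, so it is not known whether its reads align to Mir511.

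Reads counted to genes were 15664146 to 17689064 per library in MRC1+ TAMs and 10824918 to 17318957 in CD11c+ TAMs. The miR-511-3p TAMs had 23326219 to 27186233 and the mutated miR-511-3p TAMs 22906418 to 27890433. The labels number the replicates without saying whether they came from separate mice or tumours, so p-values measure only the spread between these libraries, which may be technical. Levels below are CPM, the counts relative to the library total, scaled with edgeR's TMM factors, given as mean ± SD with n = 3 per group. Log2 fold changes carry an approximate standard error (SE). It was derived as the absolute log2 fold change divided by the square root of the F statistic of edgeR's test.

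The first comparison asked which transcripts separate MRC1+ from CD11c+ TAMs. MRC1+ TAMs held more transcripts of several markers of M2-like and perivascular macrophages. Lyve1, a hyaluronan receptor, stood at 233 ± 25.0 CPM against 5.59 ± 3.11 in CD11c+ TAMs, and Cd163, the haemoglobin scavenger receptor, at 202 ± 30.2 against 9.69 ± 0.952. CD11c+ TAMs held more transcripts of dendritic cell and antigen presentation genes. Ccr7, the chemokine receptor that guides dendritic cells to lymph nodes, stood at 3.17 ± 0.699 CPM in MRC1+ TAMs against 122 ± 70.6 in CD11c+ TAMs. The chemokine gene Ccl22 stood at 2.17 ± 0.464 against 59.9 ± 33.3, and Dpp4, which encodes the surface peptidase CD26, at 1.85 ± 0.197 against 46.3 ± 5.66.

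In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2597 of 15622 tested genes passed an adjusted p of 0.05. Of these, 1080 were higher and 1517 lower in MRC1+ TAMs, and 388 and 592 differed at least 2-fold. The excess of lower genes was absent with upper-quartile scaling (1348 higher and 1325 lower) and without the first CD11c+ library (2356 and 2351). The libraries of the groups did not overlap for 38.3% of tested genes, where chance gives 10% if all libraries are exchangeable. The first principal component held 66.3% of the variance and parted the groups. On the second, which held 13.9%, the first CD11c+ library stood apart at 37.4. Without this library 4707 genes passed, 2531 of them among the 2597. Leaving out the second MRC1+, the third MRC1+ or the second CD11c+ library left 1270, 1279 and 1490 genes.

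The 10 genes with the largest increase in MRC1+ TAMs were Lyve1 (ENSMUSG00000030787, log2 fold change 5.33 ± 0.32 SE), Cd209f (5.16 ± 0.37), Cd163 (ENSMUSG00000008845, 4.38 ± 0.15), Vsig4 (4.37 ± 0.40), Bmp2 (4.05 ± 0.38), Cxcl13 (4.04 ± 0.33), Ednrb (3.67 ± 0.34), Cbr2 (3.53 ± 0.19), Chp2 (3.53 ± 0.28) and Reps2 (3.20 ± 0.23). Vsig4 encodes a complement receptor of resident macrophages, Cxcl13 a chemokine that attracts B cells and Ednrb an endothelin receptor. The highest of their values in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was adjusted p = 0.000375, for Ednrb. The 10 with the largest decrease were Sept3 (-5.85 ± 0.37), Ccl17 (-5.61 ± 0.52), Klri1 (-5.61 ± 0.25), Ccr7 (-5.27 ± 0.45), Cd209a (-5.12 ± 0.32), P2ry10 (-4.88 ± 0.30), Klrd1 (-4.83 ± 0.28), Ccl22 (-4.78 ± 0.42), Klri2 (-4.70 ± 0.22) and Dpp4 (ENSMUSG00000035000, -4.64 ± 0.15). Their highest value in the same edgeR test with Benjamini-Hochberg adjustment was adjusted p = 0.000345, for Ccl17. Klri1, Klri2 and Klrd1 encode killer-cell lectin-like receptors, and Ccl17 and Ccl22 chemokines that bind CCR4. Cd209a and Cd209f belong to a family of similar genes, so their counts can include or lose reads of relatives. All 20 genes kept their call in each fit that left out 1 library.

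**Figure D1:**
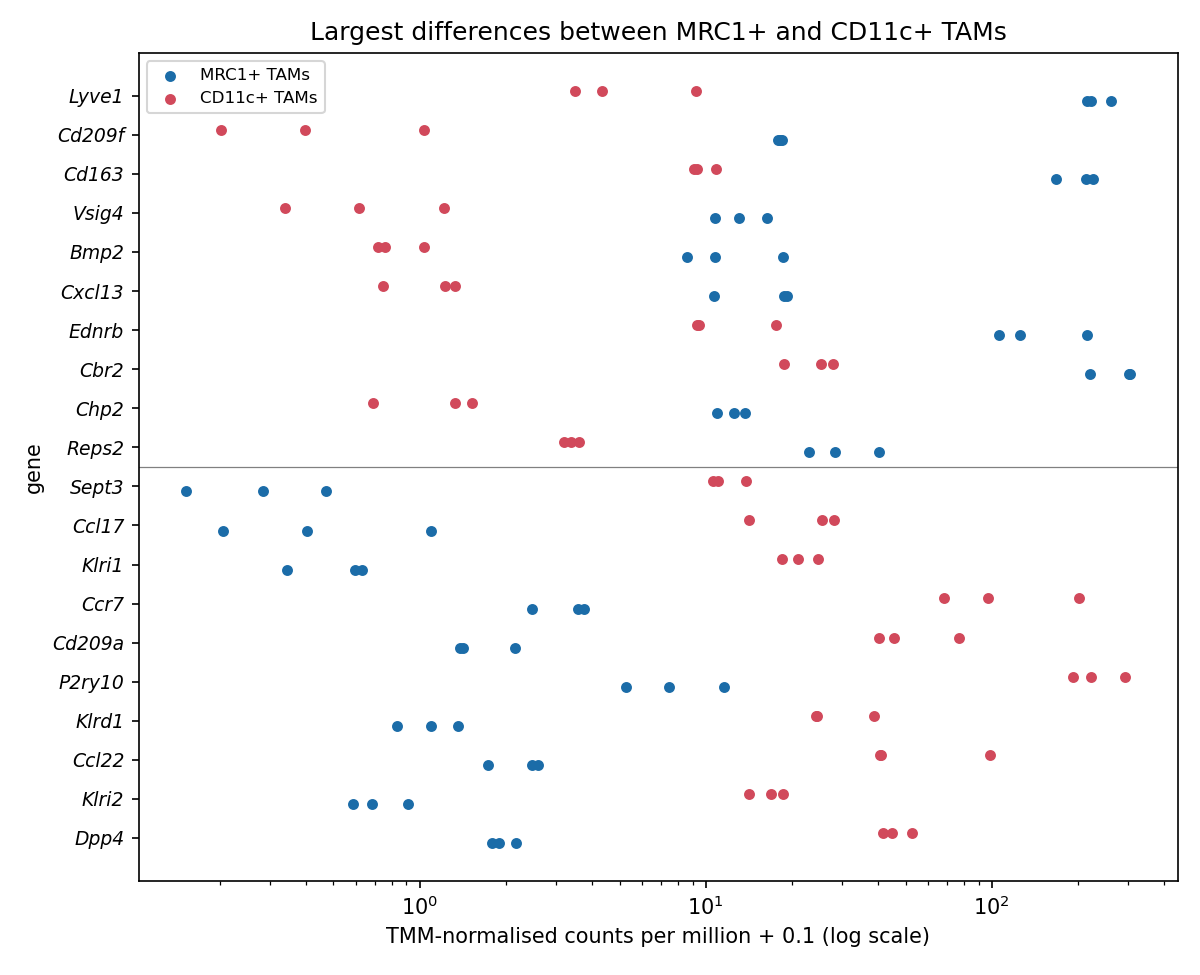
Each row is 1 of the 20 genes with the largest difference between MRC1+ and CD11c+ TAMs, and each point is 1 library on a log axis of TMM-scaled CPM plus 0.1. The 3 MRC1+ and the 3 CD11c+ libraries do not overlap for any of these genes, as for Lyve1 at 233 ± 25.0 against 5.59 ± 3.11 CPM.

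Genes of the gates followed the sort and are no finding. Mrc1 (ENSMUSG00000026712) stood at 3777 ± 279 CPM in MRC1+ TAMs against 1615 ± 193 in CD11c+ TAMs, and Itgax (ENSMUSG00000030789), which encodes CD11c, at 102 ± 22.1 against 988 ± 56.2. Adgre1, the gene of F4/80, was higher in MRC1+ TAMs by 0.80 ± 0.14 on the log2 scale, with an edgeR adjusted p = 0.00733. Csf1r, the macrophage growth factor receptor, gave -0.26 ± 0.11 and an edgeR adjusted p = 0.154, or 0.0171 without the first CD11c+ library. Rock2 gave 0.39 ± 0.14 and an edgeR adjusted p = 0.0987, which became 0.0362 when all 12 libraries shared a fit and 0.00701 without the first CD11c+ library, in a range of 0.00701 to 0.297 over the alternatives. Mir511 (ENSMUSG00000077897) had 39 reads in the MRC1+ and 8 in the CD11c+ libraries, a ratio per counted read of 4.47 with an exact 95% counting interval of 2.06 to 11.1. Its log2 fold change was 2.03 ± 0.57, with an edgeR adjusted p = 0.0453 that ranged from 0.0238 to 0.131 over the alternatives. It was 0.0683 with DESeq2, 0.0238 without the first CD11c+ library, and missed the threshold without any other library (0.0735 to 0.131). The library kit does not capture mature microRNAs, so these reads come from longer transcripts over the hairpin.

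Of the 27 lists of genes fixed before the data were examined, 14 differed from the other genes in MRC1+ against CD11c+ TAMs by camera, a competitive set test, after Benjamini-Hochberg adjustment over the lists. None of them passed with an estimated correlation between genes. That form of camera also rests its p on the few libraries instead of the many genes, so such a loss does not by itself show that genes move together. For T and NK cell markers the estimated correlation was 0.000745, below the preset 0.01, yet the unadjusted camera p went from 0.0140 to 0.0621. Fry called 9 lists, 7 of them among the 14, and left out the inflammatory, interferon, matrix, cell cycle, fibroblast, mitochondrial and ribosomal protein lists. In the list of M2-like and perivascular macrophage markers, 18 of 24 measured genes rose and 3 fell, both over all genes and adjusted over the list alone (median log2 fold change 1.52, camera adjusted p = 3.16e-12, and adjusted p = 0.239 with an estimated correlation). Besides Lyve1 and Cd163, these included Igf1, a growth factor, at 2.45 ± 0.13 and F13a1, a coagulation factor subunit, at 2.53 ± 0.14, while Mgl2 (-1.50), Timd4 (-1.26) and Chil3 (-1.03) fell. Of 11 complement genes 3 rose and none fell (4 and 1 adjusted over the list alone), with a median of 0.32, camera adjusted p = 0.0133, and adjusted p = 0.580 with an estimated correlation. They included C4b (2.46 ± 0.16) and the receptor C3ar1 (0.60 ± 0.11). Without the first CD11c+ library the complement list gave camera adjusted p = 0.0648.

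Of 21 cell cycle genes 6 rose and none fell, over all genes and adjusted over the list alone (median 0.28, camera adjusted p = 0.000134, and adjusted p = 0.581 with an estimated correlation). The mitotic genes Cdk1 (0.48 ± 0.09) and Ccnb1 (0.57 ± 0.13) were among them. Cdk1 lost its call without the third MRC1+ (edgeR adjusted p = 0.0510) or second CD11c+ library (0.0521), and Ccnb1 without any single library but the first CD11c+ (0.0568 to 0.0872). Of 8 mitochondrially encoded genes, taken as a sign of RNA quality, 2 rose (3 adjusted over the list alone), with a median of 0.46, camera adjusted p = 0.0273, and adjusted p = 0.661 with an estimated correlation. They were mt-Nd5 (0.57 ± 0.14) and mt-Nd6 (0.63 ± 0.17), and only mt-Nd5 kept its call with the replicate number as a block (mt-Nd6 adjusted p = 0.0523 in edgeR, in a range of 0.00459 to 0.156 over the alternatives). Both genes lost their call without the second or the third library of either group (edgeR adjusted p = 0.0640 to 0.123 for mt-Nd5 and 0.0711 to 0.156 for mt-Nd6), and mt-Nd6 also without the first MRC1+ library (0.0670). The list lost its call without the second MRC1+ (0.0621), the third MRC1+ (0.0908) or the first CD11c+ library (0.0648).

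Among lists that were lower in MRC1+ TAMs, 14 of 15 dendritic cell markers fell, over all genes and adjusted over the list alone (median -3.02, camera adjusted p = 4.46e-16, and adjusted p = 0.255 with an estimated correlation). They included the sort gene Itgax, and Irf4, a transcription factor of dendritic cells, at -2.66 ± 0.18. Of 11 genes of MHC class II presentation, 10 fell, again with the same count adjusted over the list alone (median -1.90, camera adjusted p = 5.20e-12, and adjusted p = 0.453 with an estimated correlation). Examples are H2-Oa (-3.99 ± 0.27), H2-Ob (-2.99 ± 0.18) and H2-DMb1 (-1.93 ± 0.17). H2-DMb1 and H2-DMb2 (-3.04 ± 0.21) are near-identical, and the counting can split their reads. Of 12 monocyte markers 8 fell and F13a1 rose, over all genes and adjusted over the list alone (median -0.96, camera adjusted p = 9.89e-05, and adjusted p = 0.537 with an estimated correlation). Ccr2, the chemokine receptor of recruited monocytes, stood at 298 ± 78.8 against 1439 ± 143 CPM, a log2 fold change of -2.27 ± 0.19.

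Of 19 inflammatory cytokine and enzyme genes 6 fell (8 adjusted over the list alone, 13 over all genes with the replicate number as a block), with a median of -0.87, camera adjusted p = 0.00121, and adjusted p = 0.661 with an estimated correlation. Il12b, a subunit of interleukin 12, changed by -3.88 ± 0.39, Il1b by -1.65 ± 0.31, and the costimulatory genes Cd80 and Cd86 by -1.48 ± 0.22 and -0.95 ± 0.16. Of 19 interferon-stimulated genes 11 fell (15 adjusted over the list alone), with a median of -0.69, camera adjusted p = 5.71e-07, and adjusted p = 0.580 with an estimated correlation. Mx1 (-1.09 ± 0.20) and the similar antiviral genes Oas3 (-0.96 ± 0.15) and Oasl2 (-0.69 ± 0.13) were examples. Of 14 sterol synthesis genes 3 fell, also adjusted over the list alone, among them Cyp51 at -0.55 ± 0.12 (list median -0.19, camera adjusted p = 0.0156, and adjusted p = 0.453 with an estimated correlation). Without the first CD11c+ library the sterol list gave camera adjusted p = 0.0600, and Cyp51 lost its call without the second or the third MRC1+ or the third CD11c+ library (edgeR adjusted p = 0.0533 to 0.0750). None of 20 ribosomal protein genes passed in either count (median -0.24, camera adjusted p = 0.0234, and adjusted p = 0.725 with an estimated correlation). The ribosomal protein list lost its call without the second MRC1+ (0.0668) or the third CD11c+ library (0.165).

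Markers of other cell types moved with these groups and with the first CD11c+ library. None of 13 fibroblast markers passed in either count, all 13 lay above 0, and the list was called higher in MRC1+ TAMs (median 0.54, camera adjusted p = 0.0156, and adjusted p = 0.661 with an estimated correlation). Of 24 collagens and matrix proteins, Tgfbi (-1.22 ± 0.15) and Fn1 (-0.97 ± 0.27), both of which macrophages themselves express, fell (1 adjusted over the list alone), while the list was called higher (median 0.56, camera adjusted p = 0.0133, and adjusted p = 0.745 with an estimated correlation). Fn1 lost its call without any MRC1+ library or the third CD11c+ library (edgeR adjusted p = 0.0539 to 0.151), in the fit of all 12 libraries (0.244) and with a filter of 5 CPM in 3 libraries (0.0509). Col14a1 gave 0.73 ± 0.26 and an edgeR adjusted p = 0.0912, or 0.00395 with the replicate number as a block, in a range of 0.00395 to 0.250 over the alternatives. The mean deviation of the fibroblast markers was 0.55 on the log2 scale in the first CD11c+ library against -0.85 and -0.72 in the other CD11c+ libraries and 0.23 to 0.41 in the MRC1+ libraries. The matrix list gave 0.73 against -0.90, -0.78 and 0.15 to 0.42. Without the first CD11c+ library the camera adjusted p became 2.69e-06 for fibroblast markers and 1.54e-10 for matrix genes. Without the second they were 0.0965 and 0.165, and without the third the matrix list gave 0.116. Of 11 T and NK cell markers Klrb1c (-1.74 ± 0.35) and Gzma (-2.10 ± 0.44) fell, also adjusted over the list alone (median -0.50, camera adjusted p = 0.0273, and adjusted p = 0.453 with an estimated correlation). Gzma lost its call without the first MRC1+ (edgeR adjusted p = 0.0534) or second CD11c+ library (0.0548), and without the latter the list gave camera adjusted p = 0.0510.

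The other 13 lists gave camera adjusted p-values of 0.104 to 0.999935, although single members passed. Scavenger and endocytic receptors split into 7 higher and 4 lower of 18 (8 and 6 adjusted over the list alone), with Stab1 at 2.14 ± 0.12 and Clec7a, a receptor for fungal glucan, at -2.38 ± 0.15. Matrix proteases and inhibitors split into 4 and 3 of 19 (6 and 4 adjusted over the list alone, 6 and 3 with the replicate number as a block), with Timp2 at 1.16 ± 0.12 and the elastase Mmp12 at -1.57 ± 0.14. Angiogenic factors split into 3 and 4 of 15 (5 and 5 adjusted over the list alone, as with the block), with Pdgfc at 1.67 ± 0.19 and Nrp1 at 1.44 ± 0.11, and their median of -0.01 and mean of 0.04 differed in sign. Lipid handling genes split into 2 and 3 of 13 in both counts, with Apoe at 0.93 ± 0.15 and Lpl at -0.71 ± 0.09, and their median of 0.12 and the direction of the test differed in sign. In hypoxia and glycolysis genes Pfkp (-0.76 ± 0.09) was the 1 of 18 to pass, in both counts, whereas Ndrg1 (-0.57 ± 0.16) and Adm (1.09 ± 0.34) passed with the replicate number as a block (edgeR adjusted p = 0.0101 and 0.0307). In immediate-early and heat shock genes Klf2 (0.37 ± 0.10) was the 1 of 21 to pass and none did adjusted over the list alone, and Jun and Nr4a1 passed with the block (edgeR adjusted p = 0.0200 and 0.00565).

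In the remaining lists of other cell types, 5 of 8 epithelial and carcinoma markers rose and 2 fell, also adjusted over the list alone (3 and 2 with the replicate number as a block). Krt18 and Hmga2 were higher by 1.13 ± 0.29 and 1.02 ± 0.25, while Cdh1 and Epcam gave -3.71 ± 0.20 and -3.72 ± 0.42, and the median of 0.97 and mean of -0.20 differed in sign. Of 6 endothelial markers 3 rose and 1 fell (4 and 1 adjusted over the list alone, 2 and 1 with the block), with Cdh5 at 1.26 ± 0.31 and Kdr at -1.07 ± 0.25. Csf3r (-0.62 ± 0.16) was the 1 of 8 neutrophil markers and Ccr3 (0.89 ± 0.25) the 1 of 6 eosinophil and mast cell markers to pass, in both counts. Ccr3 gave an edgeR adjusted p = 0.0565 with the block, and its list had a median of -0.02 and a mean of 0.09. None of 6 B cell and 8 erythroid markers passed in either count, and Ighm (-0.55 ± 0.17) passed with the block at an edgeR adjusted p = 0.0437.

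The second comparison asked which transcripts differ when TAMs overexpress miR-511-3p rather than its mutated form. Mir511 stood at 2.75 ± 0.336 CPM in miR-511-3p TAMs against 0.234 ± 0.138 in mutated miR-511-3p TAMs. This was 209 against 17 reads, a ratio of 12.008 per counted read with an exact 95% counting interval of 7.32 to 21.008. Genes of collagens and basement membrane, of fibroblasts and of T and NK cells lay lower in miR-511-3p TAMs as lists, and cell cycle genes higher, but no gene of these lists passed by itself. These list calls, made by camera, were all lost with an estimated correlation (adjusted p = 0.681 with an estimated correlation for each), and that of T and NK cells also without the third mutated library (0.0846). Nid1, a basement membrane protein, stood at 31.0 ± 15.7 against 88.1 ± 67.5 CPM, a log2 fold change of -1.50 that was -0.67 without the third mutated library, and the cell cycle gene Mcm5, a part of the replicative helicase, at 137 ± 7.52 against 118 ± 14.7.

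No gene of 14054 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 343 genes, where chance alone gives 702.7. If the numbers pair the libraries, this unpaired fit keeps their shared variation in its error, so 343 cannot be read as a deficit. DESeq2 called 1 gene, Mir511 (adjusted p = 2.40e-08), with 403 at an unadjusted p under 0.05, and limma-voom called 0, with 270. With the replicate number as a block 811 genes had an unadjusted p under 0.05 in edgeR, and with 1 library left out 155 (without the second miR-511-3p) to 740 (without the first mutated library). The edgeR fit of all 12 libraries called Mir511 (adjusted p = 0.0474), which in the fit of 6 had the lowest value, adjusted p = 0.482, at a log2 fold change of 3.56 ± 0.39 and a range of adjusted p over the alternatives of 2.40e-08 to 0.99979. With the replicate number as a block edgeR called 1 gene, Hspg2, which encodes the matrix proteoglycan perlecan and is named here only because it was that single gene. Its level was 27.5 ± 19.3 against 70.4 ± 45.0 CPM and its log2 fold change -1.39 with the block (edgeR adjusted p = 0.0271, against 0.99988 without). Libraries of the groups did not overlap for 6.38% of tested genes, where chance gives 10% if all libraries are exchangeable. Pairing by number would lower that share, so 6.38% cannot be read as a deficit. The first principal component held 46.7% of the variance and set the third mutated library, at 44.2, apart from the others.

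**Figure D2:**
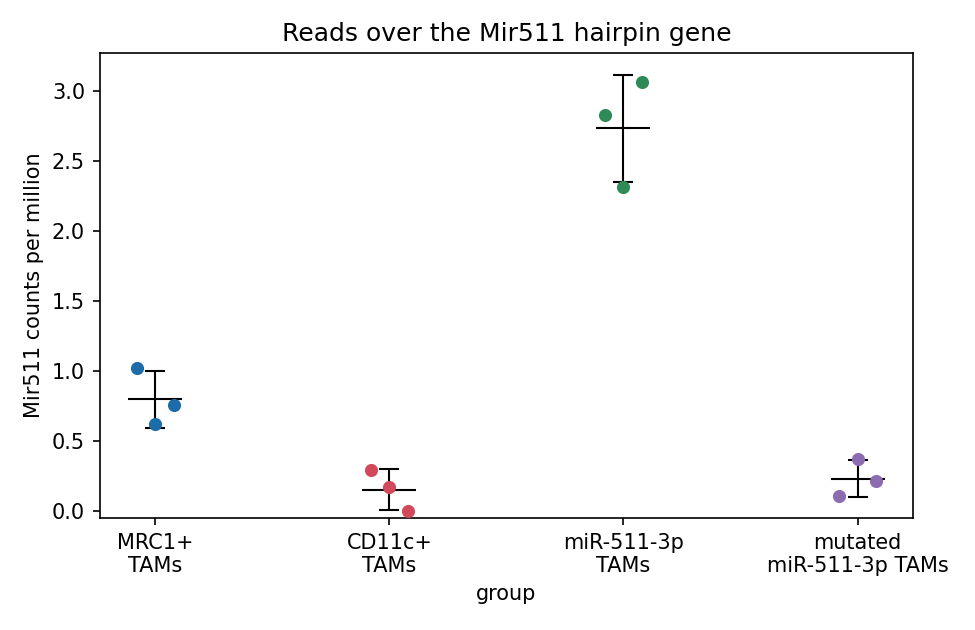
Points are Mir511 CPM in each library, not scaled by TMM factors, and the black bars are the mean and SD of each group of 3. The miR-511-3p TAMs stand at 2.74 ± 0.382, above the MRC1+ TAMs at 0.800 ± 0.203, the mutated miR-511-3p TAMs at 0.233 ± 0.134 and the CD11c+ TAMs at 0.156 ± 0.148.

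Rock2 stood at 180.1 ± 2.30 CPM in miR-511-3p TAMs against 198 ± 11.9, a log2 fold change of -0.14 ± 0.06 that did not pass (edgeR adjusted p = 0.99988). Mrc1 gave 0.29 ± 0.11, Adgre1 0.13 ± 0.11, Itgax -0.10 ± 0.38 and Csf1r 0.02 ± 0.09, none of which passed, and Adgre1 moved to 0.23 and 0.02 without the first or second miR-511-3p library. Itgax turned to 0.12 and 0.38 without the second miR-511-3p or first mutated library, and Csf1r to -0.02 without the first or the third mutated library. The other genes of lowest p with a higher value in miR-511-3p TAMs, none past the test, were Egr2 (0.34 ± 0.07), Etl4 (1.35 ± 0.31), Plk3 (0.21 ± 0.05) and ENSMUSG00000067480 (0.52 ± 0.13). On the lower side they were Ace (-1.60 ± 0.34), Sox9 (-1.68 ± 0.36), Tinagl1 (-2.25 ± 0.49), Uaca (-0.52 ± 0.12) and Nuak1 (-0.83 ± 0.19). Egr2 encodes an immediate-early transcription factor, Ace the angiotensin-converting enzyme and Tinagl1 a matrix protein.

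Of the 27 lists 9 were called by camera, none with an estimated correlation and none with fry. Over all genes no member of them passed, and adjusted over the list alone the single member to pass was Egr2. In 4 of the lists with lower values the third mutated library had the highest mean deviation. Of 23 collagens and matrix proteins 19 lay below 0 (median -1.14, camera adjusted p = 5.27e-09, and adjusted p = 0.681 with an estimated correlation). Examples are Nid1 (-1.50 ± 0.57), Col6a3 (-1.60 ± 0.61), Lum (-1.61 ± 0.61) and Col4a2 (-1.20 ± 0.47). Of 13 fibroblast markers 11 lay below 0 (median -1.25, camera adjusted p = 6.79e-07, and adjusted p = 0.681 with an estimated correlation), with Pdgfrb at -1.47 ± 0.48 and Dcn at -1.42 ± 0.60. All 8 T and NK cell markers lay below 0 (median -1.76, camera adjusted p = 7.30e-05, and adjusted p = 0.681 with an estimated correlation), with Cd8a at -2.37 ± 0.98 and Nkg7 at -1.98 ± 0.86. Of 6 epithelial and carcinoma markers 5 lay below 0 (median -0.88, camera adjusted p = 0.00229, and adjusted p = 0.681 with an estimated correlation), with the keratin genes Krt8 at -1.14 ± 0.37 and Krt18 at -0.97 ± 0.45. The third mutated library stood at 1.46 for matrix genes, 1.38 for fibroblast, 1.81 for T and NK cell and 1.02 for epithelial markers, and at 1.43 for neutrophil and 0.79 for monocyte markers, whose lists were not called. Without it the matrix and fibroblast lists gave camera adjusted p = 0.00177 and 0.00708, whereas T and NK cell (0.0846) and epithelial markers (0.0854) lost their call, the latter also without the second miR-511-3p library (0.0687). The log2 fold changes of the named members shrank without the third mutated library to between -0.40 for Krt18 and -0.86 for Pdgfrb, with Nid1 at -0.67, Dcn at -0.52 and Cd8a at -0.69. The matrix list differed by -0.75, -0.81 and -1.07 between libraries of the same number, and the fibroblast markers by -0.96, -0.61 and -1.06.

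**Figure D3:**
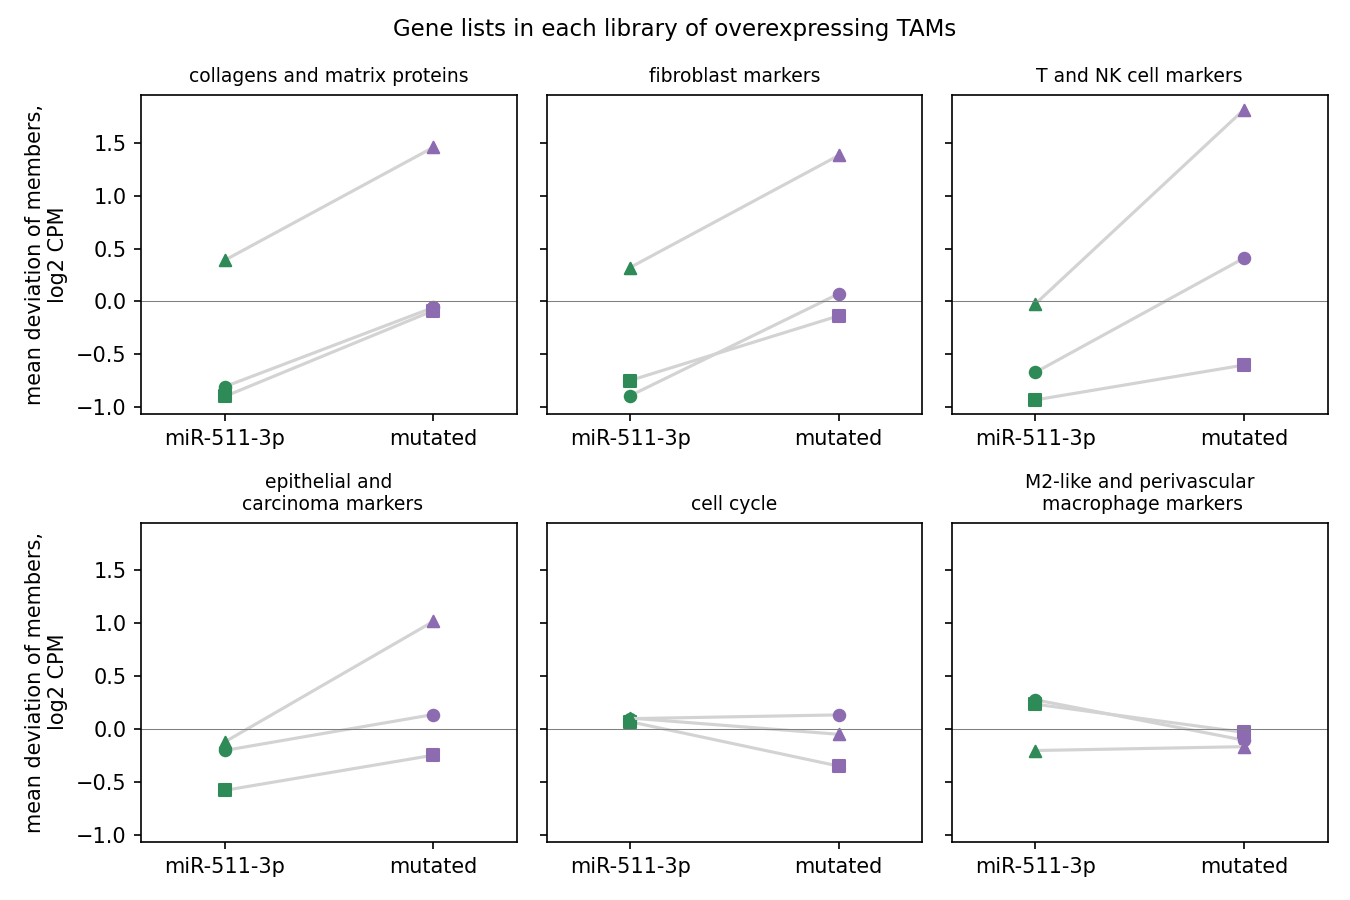
Each panel shows the mean deviation of a list's members in each of the 6 libraries, in log2 CPM, with lines and marker shapes joining libraries of the same replicate number. Matrix genes lie at -0.81, -0.90 and 0.39 in miR-511-3p TAMs and at -0.06, -0.09 and 1.46 in mutated miR-511-3p TAMs.

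Of 10 measured MHC class II genes 9 lay below 0 (median -0.14, camera adjusted p = 0.00102, and adjusted p = 0.681 with an estimated correlation), with H2-Ob at -0.32 ± 0.11 and the transactivator Ciita at -0.23 ± 0.12. Without the second mutated library this list gave camera adjusted p = 0.0942. All 21 cell cycle genes lay above 0 (median 0.17, camera adjusted p = 5.27e-09, and adjusted p = 0.681 with an estimated correlation), with Mcm5 at 0.21 ± 0.10 and Aurkb at 0.22 ± 0.11. This call held in each fit that left out 1 library, although libraries numbered 1 gave -0.04 against 0.42 and 0.15 for the others. Of 23 M2-like and perivascular markers 18 lay above 0 (median 0.22, camera adjusted p = 0.00229, and adjusted p = 0.681 with an estimated correlation), with Retnla at 2.23 ± 0.94, or 0.46 without the first miR-511-3p library, and Il10 at 0.45 ± 0.24, or 0.14 without the second. Of 21 immediate-early and heat shock genes 18 lay above 0 (median 0.14, camera adjusted p = 0.00107, and adjusted p = 0.798 with an estimated correlation), with Zfp36 at 0.19 ± 0.09 and Hspa1a, which shares reads with Hspa1b, at 0.37 ± 0.26. Without the second miR-511-3p library Zfp36 stood at 0.10 and Hspa1a at 0.05, and without the second mutated library Mcm5 stood at 0.12 and Aurkb at 0.10. Ciita was -0.35 without the first and -0.15 without the third mutated library. The M2-like list lost its call without the second miR-511-3p (0.237) or the third mutated library (0.0854), and the immediate-early list without the second miR-511-3p (0.832) or the first mutated library (0.889). Of 20 ribosomal protein genes 15 lay above 0 (median 0.04, camera adjusted p = 0.0498, and adjusted p = 0.798 with an estimated correlation). This last call was lost without the first (0.0858) or the third miR-511-3p (0.441) or the first (0.601) or second mutated library (0.0942).

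The other 18 lists gave camera adjusted p-values of 0.0593 to 0.956 with no member past the test in either count. All 5 erythroid markers lay below 0 (median -0.70, camera adjusted p = 0.0593), and with the replicate number as a block the list gave camera adjusted p = 1.54e-06. No list passed with the block and an estimated correlation, and without the block the erythroid list gave adjusted p = 0.798 with an estimated correlation. Matrix proteases and inhibitors had a median of -0.01, angiogenic factors -0.05, scavenger receptors 0.09, complement 0.06, sterol synthesis -0.04, lipid handling -0.05 and hypoxia and glycolysis 0.02. Dendritic cell markers had a median of -0.12, monocyte markers -0.17, inflammatory genes 0.07, interferon-stimulated genes 0.03 and mitochondrially encoded genes -0.03. Neutrophil, endothelial, and eosinophil and mast cell markers gave -0.63, -0.11 and 0.33, and the 3 measured B cell markers had a median of 0.06 but a mean of -0.26.

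Another question was whether the genes that part MRC1+ from CD11c+ TAMs moved as sets under miR-511-3p. The 998 measured genes higher in MRC1+ TAMs had a median log2 fold change of 0.00, with 50.7% above 0, and the 1427 lower in MRC1+ TAMs -0.01, with 47.9% above 0. Neither set passed in camera, at adjusted p = 0.651 for both with Benjamini-Hochberg adjustment over the 2 sets, and the mean of the first was -0.08, opposite in sign to its median. Limited to genes with at least a 2-fold difference between the sorted groups, the set lower in MRC1+ TAMs gave a camera p of 0.0321, lower under miR-511-3p. With sets from the sorted comparison without the first CD11c+ library, chosen after the data had been seen, the 2106 measured genes higher in MRC1+ TAMs lay lower under miR-511-3p (median -0.06, 62.9% below 0, a camera p of 1.44e-07). This p was 0.0790 with an estimated correlation. The direction of the set higher in MRC1+ TAMs turned without the third miR-511-3p library, and that of the set lower in them without the second miR-511-3p or the first mutated library (camera p of 0.281, 0.785 and 0.576). Across 13740 genes, which are not independent replicates, the log2 fold changes of the 2 comparisons had a Pearson r of -0.131 and a Spearman correlation of -0.0973. Without the third mutated library r was -0.0428, and without the first miR-511-3p library -0.0755.

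The last question was whether genes with a miR-511-3p site lay lower under miR-511-3p. The mature sequence, AATGTGTAGCAAAAGACAGGAT in DNA letters, was found at bases 49 to 70 of the Mir511 hairpin in the reference annotation, and its seed pairs with the heptamer TACACAT in a 3′ UTR. Of 11887 tested genes with a known 3′ UTR (2372 with a site and 9515 without), those with a site had a mean log2 fold change of -0.08 and those without -0.05. Camera placed the site genes lower with a p of 0.0147, or 0.00546 with an estimated correlation, though this p was 0.0534 without the third miR-511-3p and 0.0967 without the third mutated library. Site genes had longer 3′ UTRs, with a median of 2440.5 bases against 937. Matched on 3′ UTR length the difference was -0.01, rank 24 from the lowest among 210 heptamers of the same base composition, where the lowest 5% end at rank 10. The matched difference therefore did not pass, except among genes above the median expression (rank 1) and without the third mutated library (rank 10). The difference itself was smaller in these settings, at -0.0116 and -0.00960 against -0.0142. Leaving out the first or the second mutated library gave rank 63 or 44. With only 7mer-m8 and 8mer sites the rank was 56.

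**Figure D4:**
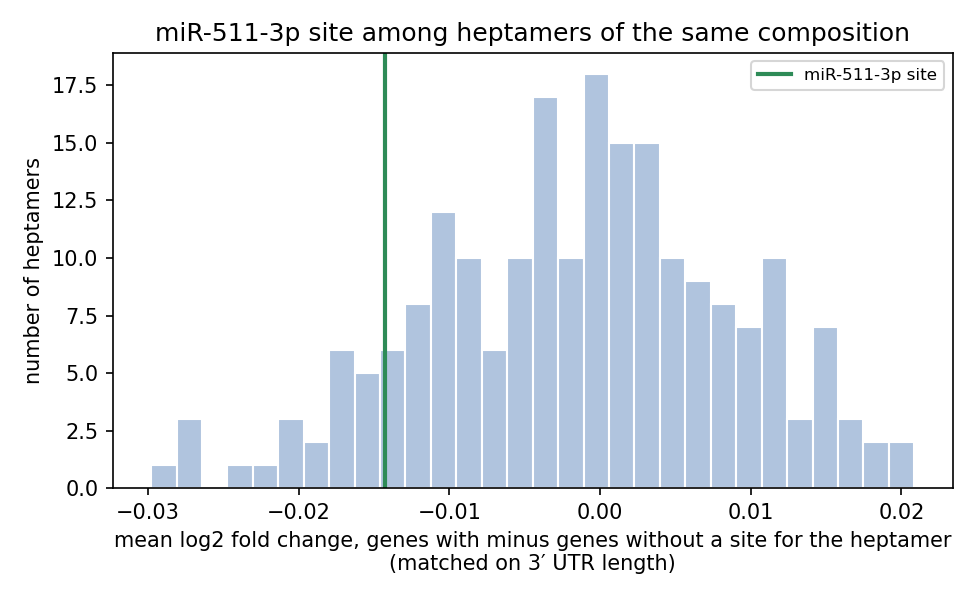
The histogram counts 210 heptamers of the same base composition by the mean log2 fold change of genes with minus genes without a site for the heptamer (8mer, 7mer-m8 or 7mer-A1) in their 3′ UTR, matched on 3′ UTR length. The green line marks the miR-511-3p site, rank 24 from the lowest.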

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

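The tests of the depth of the third mutated library, of fibroblast markers outside the matrix list and of Mir511 reads against Mrc1 counts, and the sets made without the first CD11c+ library with their estimated correlations, were chosen only after the results concerned had been seen. Groups of 3 are too small to test a single library for standing apart.

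The lists of matrix genes and of fibroblast, T and NK cell and epithelial markers were called lower in miR-511-3p TAMs by camera. None was called with an estimated correlation (adjusted p = 0.681 with an estimated correlation for each). All were highest in the third mutated library. The T and NK cell (camera adjusted p = 0.0846) and epithelial (0.0854) calls were lost without that library, whereas the matrix (0.00177) and fibroblast (0.00708) lists kept theirs. Both of the latter were lower under miR-511-3p in all 3 pairs of the same number, but that pairing was itself drawn from these data. Unpaired, the third miR-511-3p library (0.39 for matrix genes, 0.32 for fibroblast markers) stood above the first (-0.06 and 0.07) and second mutated libraries (-0.09 and -0.14). Whether the third mutated library alone accounts for both lists is therefore not settled. For the matrix list direct miR-511-3p sites are argued against, since 3 of 23 matrix genes held one (13.04%, against 19.97% of 11864 other genes and 16.2% of those of similar 3′ UTR length, one-sided Fisher exact p = 0.866). Sites in the other lists were not tested. Low depth of the third mutated library is also argued against, since a library 1.02 times as deep lay at the opposite end of the first principal component. In the third mutated library Col3a1 stood at 467 CPM and Dcn at 57.6, and the 8 fibroblast markers that are not in the matrix list had a median log2 fold change of -1.16 against -1.14 for the matrix genes. The deviation of the third mutated library correlated across 13740 genes with that of the first CD11c+ library, which also held more fibroblast marker RNA, at 0.392, against at most 0.288 for the other overexpression libraries. A candidate explanation is therefore RNA of other tumour cells, in amounts that differed between libraries although the sort for F4/80 would remove most such cells. An effect of miR-511-3p on the surrounding cells or on matrix genes of macrophages stays open and untested. It also stays open that uneven libraries fell into the groups by chance. Of the 10 ways to split these libraries into groups of 3, 7 called at least 9 lists, the real split included.

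The log2 fold changes of the 2 comparisons correlated negatively across genes, at -0.131, although the genes higher in MRC1+ TAMs did not differ from the others as a set (camera p of 0.651). Without the third mutated library the correlation was -0.0428, so RNA of other cells in that library may account for part of it, but it was also closer to 0 without the first miR-511-3p library, at -0.0755. The set of genes higher in MRC1+ TAMs that was made without the first CD11c+ library lay lower with a camera p of 1.44e-07, and without the third mutated library with a p of 0.00419 (median log2 fold change -0.04, 59.3% below 0). With estimated correlations, of 0.0526 and 0.0157, these camera p-values became 0.0790 and 0.104 and did not pass. The second correlation is close to the preset 0.01, and this form of camera rests its p on the few libraries instead of the many genes. The loss therefore does not show that the genes move together, and whether the set lies lower without that library is not settled. RNA of other cells, which this set can take up since the library with most fibroblast marker RNA was left out, and an effect of miR-511-3p on genes of MRC1+ TAMs both stay open.

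Mir511 reads were higher with overexpression, far beyond the host gene, with a lower bound of the ratio of 7.32 against a ratio of 1.21 for Mrc1, so transcription of Mrc1 alone is argued against. Between MRC1+ and CD11c+ TAMs the ratio of 4.47 had an interval of 2.06 to 11.1 that held the Mrc1 ratio of 2.55, which is consistent with shared transcription. Per count of Mrc1 the miR-511-3p TAMs had 5.91 times the Mir511 reads of MRC1+ TAMs (4.18 to 8.54), and the mutated miR-511-3p TAMs 0.592 times (0.314 to 1.07). The reads of the mutated hairpin may be missing from the Mir511 counts, or the vector may express little of it, and the counts do not part these. Nor does the ratio show either, because the set-ups differ. Reads over no gene averaged 24.7% in MRC1+ and 8.87% in mutated miR-511-3p libraries. Mir511 lies within an intron of Mrc1, so its endogenous reads per count of Mrc1 may differ between the set-ups as well.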

How the results depend on the processing

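The newer quasi-likelihood method, lists without Mrc1 and Itgax, the block combined with fry or an estimated correlation, and sets without the first CD11c+ library were chosen only after the data had been seen. Every alternative chosen beforehand was run, and where a value moved the cause was not tested unless fewer libraries or genes entered. The count of 2597 genes between MRC1+ and CD11c+ TAMs was 2292 to 3325 under other scalings, filters, tools and a fit of all 12 libraries, 2135 to 2589 of them shared, and 2788 with the replicate block (2359 shared). It was 980 with at least a 2-fold change, 4054 at an adjusted p below 0.10, and 1270 (without the second MRC1+) to 4707 (without the first CD11c+) with 1 library left out, with 1279 and 1490 without the third MRC1+ and second CD11c+ library. Of the fixed lists 14 were called, 14 with the block, 12 to 16 with 1 library left out, 9 with fry, 4 with the block and fry, and 0 with an estimated correlation with or without the block. Under miR-511-3p no gene was called except 1 each with DESeq2, with the fit of all 12 libraries and with the block. The 9 lists called there became 10 with the block, 6 to 12 with 1 library left out, and 0 with fry or an estimated correlation, each with or without the block. The set of genes higher in MRC1+ TAMs gave a camera p of 0.234 to 0.947 with 1 library left out, turning direction without the third miR-511-3p library (0.281), and 1.44e-07 when made without the first CD11c+ library. The set lower in MRC1+ TAMs gave 0.203 to 0.785, turning direction without the second miR-511-3p (0.785) or first mutated library (0.576) and when made without the first CD11c+ library (0.434), and passed at 0.0321 when limited to 2-fold changes. The correlation across genes was -0.150 to -0.0428 with 1 library left out, with -0.0755 without the first miR-511-3p and -0.0428 without the third mutated library, and -0.129 with the block. The camera p of the site genes was 0.0184 to 0.0967 with 1 library left out, missing the threshold without the third miR-511-3p (0.0534) and the third mutated library (0.0967), and 0.0195 with the block. Their rank was 10 to 63 with 1 library left out, 27 with the block, 25 with 8mers, 56 with 7mer-m8 and 8mer sites, 15 with the shortest 3′ UTR and 1 among genes above the median expression. Itgax under miR-511-3p was -0.39 to 0.38, above 0 without the second miR-511-3p (0.12) or first mutated library (0.38), and Csf1r -0.0228 to 0.11, below 0 without the first (-0.0228) or the third mutated library (-0.02). Of the values for named genes under other settings, 1061 kept direction and side of the threshold, 30 newly passed and 5 no longer did. With 1 library left out these were 679, 14 and 47, and 4 turned direction. Of genes not discussed with their lists, C5ar1, Gzmb and Rps4x passed with the block. With it 20 M2-like markers and 7 cell cycle genes were higher, against 18 and 6 without, and scavenger receptors split into 8 and 3, against 7 and 4. Other scalings moved the median of all genes by -0.00406 and 0.0514 (log2) in the sorted and -0.00365 and -0.00781 in the overexpression comparison. With 3 libraries per group and this depth, Mir511 rests on few reads. A difference that was not called may be absent or may be too small or too variable to detect here, and not only for genes of few reads.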

Other observations

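The splits that count genes, and the bound of 1 SD between a heptamer and the limit of the lowest 5%, were chosen only after the result was seen. Endogenous miR-511-3p might lower the transcripts with its sites in MRC1+ TAMs, where Mir511 reads were higher. Matched on 3′ UTR length, genes with a site for the heptamer TACACAT differed from those without by -0.02 on the log2 scale in MRC1+ against CD11c+ TAMs. This was rank 35 from the lowest of 210 heptamers of the same base composition, outside the lowest 5%, so a lowering was not shown. The difference lay above the limit of the lowest 5% by 0.587 SD of the heptamers, and the hypothesis stays open.

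The overexpressed hairpin could also release the 5p arm, miR-511-5p, whose sites pair with the heptamer AAAGGCA. Matched on 3′ UTR length, genes with such a site differed by 0.00393 on the log2 scale between miR-511-3p and mutated miR-511-3p TAMs. This was rank 96 of 105 heptamers of the same composition and 2.83 SD above the limit of the lowest 5%, so no lowering between these groups was shown. The sequence of the mutated hairpin is not known here. If it releases the same 5p arm, an effect of that arm would cancel, so the comparison cannot decide the question. Not matched on length, genes with such a site, whose 3′ UTRs are longer (median 2399 bases against 907.5), gave a camera p of 0.188, lower under miR-511-3p, or 0.00577 with an estimated correlation.

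The 6 libraries of a comparison can be split into groups of 3 in 10 ways, too few for a share under 0.05. In the sorted comparison 1 of the 10 splits gave as many as 2597 genes, the real one, and the highest other gave 0. The other splits mix MRC1+ and CD11c+ libraries within a group, which adds their difference to the spread. Their count of 0 is therefore no measure of what chance gives. As many as 14 lists came from 1 split, with 13 in the highest other, a split that parts all 3 pairs of libraries of the same number as the real one does. In the miR-511-3p comparison all 10 splits gave 0 genes. At least 9 lists came from 7 of the 10 splits, with 14 in the highest other, which parts 1 pair, and 10 in the highest other that parts all 3. For genes with a miR-511-3p site 1 split gave a camera p as low as 0.0147, and the lowest other was 0.134, from a split that parts all 3 pairs. For the set higher in MRC1+ TAMs 10 splits gave a p as low as 0.651, with 0.0625 in the lowest other, and for the set lower in MRC1+ TAMs 8 gave a p as low as 0.549, with 0.0203 in the lowest other, both from a split that parts all 3 pairs.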
